A study of Taeniopygia guttata with 4 samples.

How the data were processed

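Single nuclei were isolated from 2 brain nuclei of the adult male zebra finch song system, HVC and RA (the robust nucleus of the arcopallium), which HVC projects to. Per the labels' protocols, birds were 173 to 202 days old, tissue was taken at midday (hours 12 to 14), and each region was cut by hand from 200 µm sagittal slices. Frozen pieces from several birds were pooled before the nuclei were extracted, and libraries were made with a Chromium 3' kit. There were 3 HVC libraries and 1 RA library. The labels do not say how many birds went into each pool or whether the HVC libraries came from separate birds, so p-values measure only the spread between these libraries, which may be technical.

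The deposited tables hold UMI counts per barcode and gene, made by the authors with Cell Ranger per the submitters' processing notes, with no normalization. The version of Cell Ranger, the genome build and the gene annotation are not given in the sources used here. Each table lists the same 17430 genes, of which 14083 have a symbol in the RefSeq table of the bTaeGut7.mat assembly and 4643 carry an LOC identifier; that assembly was used for symbols only. Strand handling in counting is not stated, so genes that overlap on opposite strands, such as ND6 in the mitochondrial genome, and closely related copies are uncertain. At most 30 barcodes were shared between any pair of libraries.

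Barcodes with fewer than 500 genes or more than 5% mitochondrial UMIs were dropped (255, 116, 0 and 95 barcodes under the gene minimum and 14, 19, 198 and 8 over the mitochondrial maximum in HVC libraries 1, 2 and 3 and RA). Doublets were scored per library with scanpy's Scrublet. Its automatic threshold marked 1, 1 and 3 barcodes in the HVC libraries and 359 in RA, so it had not worked for HVC. After this was seen, the highest scores were dropped in each library at a rate of 0.8% per 1000 barcodes, which removed 890, 716, 739 and 278 further barcodes. The nuclei kept numbered 9395, 8616 and 8675 in HVC and 5520 in RA.

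Counts were scaled to 10000 per nucleus and log-transformed. Clusters were found from 3000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1, with no batch correction, and the genes of the fixed lists were left out of the variable genes. This gave 44 clusters. Markers of each class were fixed (16 marker lists, 114 of 130 genes in the tables); the scoring rule was built after the clusters were seen. A cluster took the name of the class with the highest score, the mean over markers of its level relative to the highest cluster, if at least 3 markers reached 20 CPM (counts scaled to library size) and a ratio of 0.25 to the highest cluster, and if the best score was at least 1.2 times the next. An earlier rule, a fold against the median cluster, could not name an RA glutamatergic cluster. A rule with no step for weak markers named cluster 15 an astrocyte cluster, and a weak-marker step relative to the best score dropped an RA glutamatergic cluster. The rule used here leaves a cluster unnamed if none of its class's markers is among its 10 leading genes and its score is under 0.6 of the median score of that class. Clusters with a median doublet score of at least 0.12, clusters of mixed droplets (mean mitochondrial share over 1.5% and no marker of the best class among the leading genes), clusters led by another class's markers and clusters with markers of 2 classes also stayed unnamed. Names below are cell-type-like names from these markers and not an annotation by the authors. GABAergic nuclei of all libraries and HVC glutamatergic nuclei were clustered again at resolution 0.5; GABAergic subclasses were named for the ganglionic eminence (medial, caudal or lateral; MGE, CGE, LGE) from the same kind of list.

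Counts were summed per library and class and tested with edgeR's quasi-likelihood test (filterByExpr, TMM, robust fit) with Benjamini-Hochberg adjustment at 0.05, for classes with at least 20 nuclei in every library. Changes are log2 RA over HVC and the SE is the size of the change over the square root of F. RA is 1 library, assumed to vary like the HVC libraries. The fit draws each gene's spread towards a spread shared over genes, with a weight given by the prior degrees of freedom. Their median was 4.46 in glutamatergic neurons, 9.17 in astrocytes, 11.5 in GABAergic neurons, 76.2 in oligodendrocyte precursors and 116 in endothelial cells. It was infinite in oligodendrocytes and microglia. The size of p-values can therefore not be compared between classes. An exact permutation test of 1 library against 3 cannot give a p under 0.25, so it was not used. Shares of classes were tested with the same tool on numbers of nuclei, with exact Clopper-Pearson 95% intervals for single libraries, which cover counting error only. Where a count is 0, the upper limit is 3 counts over the group, and folds are given against that floor. Ratios resting on 1 to 3 counts have exact 95% counting intervals. The difference between glutamatergic and GABAergic neurons in the RA against HVC change was tested as an interaction with the library as a block. HVC glutamatergic clusters were each set against the other HVC glutamatergic nuclei with the library as a block, and only fixed-list genes, which took no part in the clustering, are given. Distances between libraries are root mean square log2 differences in CPM over genes with a mean of at least 20 CPM, after adding 10 CPM, at 104 nuclei per library and class and equal UMIs, as the mean of 5 draws.

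The 18 gene lists (401 of 451 members in the tables) covered potassium channels, sodium, calcium and HCN channels, glutamate receptors, GABA and glycine receptors, axon guidance, cadherins, cortical layer transcription factors, activity-induced genes, neuropeptides and their receptors, steroid and retinoid signalling, calcium-binding proteins, trophic factors and receptors, monoamine and acetylcholine receptors, immature neuron genes, astrocyte reactivity, myelination, heat shock and dissociation stress, and mitochondrial transcripts. Each was tested in each class with limma's camera (preset correlation 0.01, lists with at least 5 members), adjusted over lists and classes, and again with an estimated correlation and with fry. The groups, tests, lists, markers and the rule for named genes were fixed before the data were examined. That rule took, among genes past the threshold with a mean of at least 20 CPM and RA outside the range of the HVC libraries, the 8 highest and 8 lowest changes in each neuron class, the 4 highest and 4 lowest in other classes, up to 4 members of each list by adjusted p in neurons, up to 3 list genes higher and 3 lower per HVC cluster, and the 6 largest interactions. Identifiers with no symbol were counted and not named. Some genes that the rule took are not reported.

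Alternatives fixed at the same time were RLE size factors, DESeq2, no filter on low counts, at least 1000 genes per nucleus, doublets kept, other Leiden resolutions (0.5 for all nuclei, 0.3 for HVC glutamatergic and 1 for GABAergic nuclei), list genes used for clustering, equal nuclei and UMIs, each HVC library left out in turn, no block, and other distance measures. Chosen after seeing the data were shares out of named nuclei, naming without the weak-marker step, calls at least as high in a class as in glutamatergic neurons, neurons matched in depth alone, GABAergic subclasses fitted one by one, each library set against the others, levels of genes higher in RA as a percent of the glutamatergic level, calls shared with glutamatergic neurons against the number for independent lists, and the first clusters in place of the second clustering.

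Software was R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The tests were tested on simulated data with the design and means of the real libraries, 1 simulation per fit with 200 genes changed. In glutamatergic neurons the test found 44% of genes changed by a log2 of 1 and 80% of those changed by a log2 of 2, and 10.1% of its calls were false. The matching values were 44%, 84% and 11.7% in GABAergic neurons, 29%, 90% and 11.9% in astrocytes, 32%, 67% and 9.17% for the interaction, 84%, 96% and 9.55% for HVC subcluster 1 and 63%, 85% and 6.92% for subcluster 12. In smaller classes they were 25%, 83% and 6.09% in oligodendrocytes, 26%, 71% and 4.90% in oligodendrocyte precursors, 21%, 72% and 8.82% in endothelial cells and 13%, 56% and 11.5% in microglia. With no list changed, camera called 1 list in the glutamatergic simulation and 0 in the others. Genes were drawn independently there, so the simulation cannot check camera's calls where members of a list are correlated. With no difference between regions the simulated distance ratio was 1.00, and 1.07 with the changed genes.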

Results

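Nuclei from HVC (3 libraries) and RA (1 library) of adult male zebra finches were compared to ask how cell types and their expression differ between these 2 regions of the song motor pathway. The tables held 10554, 9467 and 9612 barcodes for HVC libraries 1, 2 and 3 and 5901 for RA, with 39126315, 37963743, 38142454 and 19227176 UMIs. The median UMIs per barcode were 2897, 3238 and 3135.5 in HVC and 1723 in RA. After filters 32206 nuclei were kept. Named classes took in 8143, 7327, 3546 and 5196 of them.

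Ependymal-like cells made up 2.00% ± 0.265 (SD, n = 3) of kept HVC nuclei and 0 of 5520 RA nuclei, which allows a share of up to 0.0543%, so they were at least 36.7-fold lower in RA (edgeR, Benjamini-Hochberg adjusted p = 0.000509). Immature-neuron-like cells made up 2.62% ± 0.962 of HVC nuclei and 3 RA nuclei (0.0543%, exact interval 0.0112 to 0.159), a ratio of 48.2-fold (counting interval 16.4 to 234; edgeR adjusted p = 0.00157). Mural-like cells went the other way, with 0.262% ± 0.122 in HVC and 2.36% in RA (log2 change 3.16 ± 0.78 SE, edgeR adjusted p = 0.00192). These calls held with each HVC library left out. The mural share leaves out unnamed cluster 17, which scored highest for mural markers (0.866) but had erythrocyte genes among its leading genes. It held 57, 31 and 476 nuclei in HVC libraries 1, 2 and 3 and 31 in RA, against 70 HVC nuclei in the named mural class. In HVC library 3 it was 5.49% of nuclei, above the mural share of RA. The mural difference was not tested with these nuclei included, so it depends on how they are named. At a Leiden resolution of 0.5 the immature neuron share no longer passed (log2 -2.06, edgeR adjusted p = 0.163).

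Shares of the common classes varied widely between the HVC libraries. Oligodendrocytes were 2.91% ± 1.43 in HVC and 10.5% in RA (log2 1.84 ± 0.77 SE, edgeR adjusted p = 0.0552), astrocytes 10.4% ± 3.72 and 27.6% (log2 1.41, adjusted p = 0.151), oligodendrocyte precursors 1.77% ± 0.491 and 4.20% (log2 1.25, adjusted p = 0.197), and endothelial cells 3.24% ± 1.92 and 7.25% (log2 1.16, adjusted p = 0.211; -0.58 with at least 1000 genes per nucleus). Glutamatergic neurons were 35.7% ± 12.9 in HVC and 24.7% in RA (log2 -0.53, edgeR adjusted p = 0.594), GABAergic neurons 10.8% ± 4.33 and 16.1% (log2 0.57, adjusted p = 0.590), and microglia 1.11% ± 0.514 and 1.39% (log2 0.33, adjusted p = 0.694). Much of that spread came from HVC library 3, in which 59.1% of nuclei stayed unnamed, against 1252 of 9395 and 1289 of 8616 nuclei in the other HVC libraries and 5.87% in RA (log2 -2.31, edgeR adjusted p = 0.0552). Without library 3 the shares of astrocytes (log2 1.14, edgeR adjusted p = 0.0186), glutamatergic neurons (log2 -0.80, adjusted p = 0.0202), oligodendrocyte precursors (log2 1.04, adjusted p = 0.0186), oligodendrocytes (log2 1.53, adjusted p = 0.0482) and unnamed nuclei (log2 -1.27, adjusted p = 0.0186) passed. Out of named nuclei alone, a denominator chosen after the data were seen, astrocytes were 14.8% ± 0.875 and 29.3% (edgeR adjusted p = 0.0054) and glutamatergic neurons 50.5% ± 0.464 and 26.3% (edgeR adjusted p = 0.0054). With that denominator oligodendrocytes (log2 1.46, edgeR adjusted p = 0.0147) and oligodendrocyte precursors (log2 0.81, adjusted p = 0.0203) also passed. Depth can set which nuclei pass the gene minimum: the median UMIs in glutamatergic neurons were 4077 ± 202 in HVC and 6682.5 in RA, but 1596 ± 88.0 and 1280 in astrocytes.

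**Figure D1:**
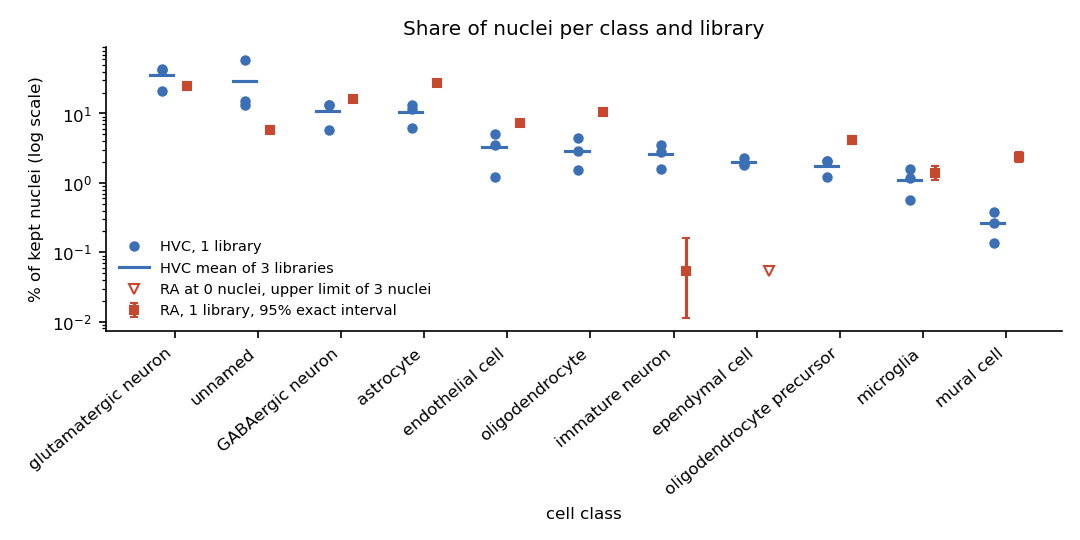
Percent of kept nuclei (log axis) in each class, with 1 circle per HVC library, a line at the mean of the 3 HVC libraries and a square for RA with its exact 95% interval. The open triangle marks the upper limit of 0.0543% for ependymal cells in RA. Mural cells, without unnamed cluster 17, stood at 2.36% in RA against a mean of 0.262% in HVC.

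Unnamed nuclei fell into clusters of doublet-like nuclei (6.33%, 8.72% and 4.52% of HVC libraries 1, 2 and 3 and 5.13% of RA), mixed droplets (3.09%, 3.48%, 47.5% and 0.0906%), clusters led by another class's genes (0.607%, 0.360%, 5.49% and 0.562%), clusters with markers of 2 classes (0.117%, 0.151%, 0% and 0.0906%) and cluster 15, with weak astrocyte markers (3.18%, 2.25%, 1.63% and 0 of 5520). The step that left cluster 15 unnamed was set after the clusters were seen.

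Among neurons, GABAergic nuclei were 22.9% ± 1.10 (SD, n = 3) in HVC and 39.3% in RA (exact interval 37.3 to 41.4). Within GABAergic nuclei, CGE-like cells, whose markers include RELN and ADARB2, were 8.55% on average in HVC and 20.9% in RA (log2 1.30 ± 0.38 SE, edgeR adjusted p = 0.0356). LGE-like cells were 30.5% ± 9.81 and 22.8% (log2 -0.43, edgeR adjusted p = 0.409), MGE-like cells 44.0% ± 5.45 and 44.5% (log2 0.02, adjusted p = 0.965), and unnamed subclasses 16.9% ± 4.49 and 11.9% (log2 -0.50, adjusted p = 0.409). Most MGE-like nuclei lay in subclusters 1, 3, 4, 7 and 13 in HVC and 5, 9 and 18 in RA, and most LGE-like nuclei in subclusters 0 and 2 in HVC and 6 in RA. The CGE call was lost without HVC library 1 (log2 1.24, edgeR adjusted p = 0.257) or library 2 (log2 1.24, adjusted p = 0.280), and the LGE share passed without library 3 (log2 -0.66, adjusted p = 0.0477).

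Glutamatergic neurons, the class with the projection neurons of both regions, differed in 3988 of 13804 genes (28.9%; edgeR adjusted p under 0.05), with 1933 higher and 2055 lower in RA. They lay in clusters 0, 3, 6, 16, 26 and 27 in HVC and 8 and 20 in RA. The largest rise among named genes was in SLC18A2, the vesicular monoamine transporter, from 0.626 ± 0.116 CPM (SD, n = 3) in HVC to 95.7 CPM in RA (log2 7.30 ± 0.20 SE, edgeR adjusted p = 2.34e-05). TSHZ3, a zinc finger transcription factor, rose from 8.98 ± 1.35 to 920.1 CPM (log2 6.69 ± 0.17 SE, edgeR adjusted p = 2.34e-05). The secreted neurotrophic protein NDNF (log2 7.02), the solute carrier SLC4A11 (6.87), FNDC1 (6.77), the laminin chain LAMA3 (6.63), the collagen chain COL15A1 (6.47) and the cGMP phosphodiesterase PDE5A (6.45) also rose, with SE from 0.19 to 0.43 and edgeR adjusted p from 2.34e-05 to 0.000408.

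Lower in RA glutamatergic neurons were LRTM1 (log2 -7.34 ± 0.35 SE), the cytolinker PPL (-6.95 ± 0.54), the retinoic acid synthesis enzyme ALDH1A2 (-6.60 ± 0.46; 397 ± 101 CPM in HVC and 4.09 in RA) and the chloride channel CFTR (-5.74 ± 0.46), with edgeR adjusted p from 0.000117 to 0.000714. A further 4 genes had 3 counts or fewer in RA. The peptide gene UTS2B was 657-fold lower (counting interval 118 to 25961), LGR6, a receptor for R-spondins, 448-fold (124 to 3701), the small GTPase RAB37 306-fold (54.8 to 12089) and FNDC9 102-fold (34.8 to 495). Without HVC library 1 UTS2B no longer passed (edgeR adjusted p = 0.0635), and the class count fell to 2571 genes. The free-RNA background was high for the class marker SLC17A6, the vesicular glutamate transporter, which reached 17.0% to 42.8% of its glutamatergic level in the other HVC classes and 9.91% to 29.5% in those of RA.

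**Figure D2:**
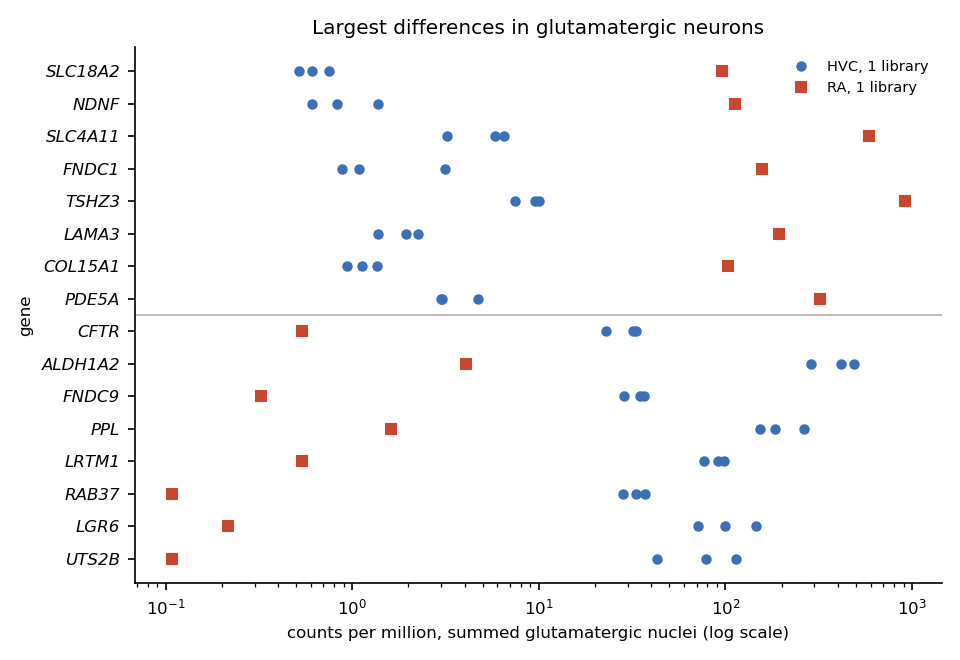
CPM (log axis) of the 8 highest and 8 lowest named genes in summed glutamatergic nuclei, with 1 circle per HVC library and a square for the RA library. TSHZ3 stood at 8.98 CPM on average in HVC and 920.1 in RA, and ALDH1A2 at 397 and 4.09.

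Ion channel and receptor genes of glutamatergic neurons went both ways. Of 35 potassium channel genes 8 rose, 14 fell and 13 did not pass, or 12 and 16 adjusted over the list alone. KCNB2 (log2 3.66 ± 0.13 SE) and KCNK10 (2.99 ± 0.17) rose, KCNH1 (-1.57 ± 0.13) and KCNH7 (-1.74 ± 0.15) fell, and camera made no call (adjusted p = 0.348). Of 23 sodium, calcium and HCN channel genes 7 rose and 6 fell, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.532; median 0.18, mean -0.31, test direction lower). The calcium channel subunits CACNA2D3 (-4.39 ± 0.27), CACNA1I (-3.91 ± 0.35) and CACNA1E (-1.94 ± 0.14) fell and CACNA1G (1.84 ± 0.17) rose. Of 24 glutamate receptor genes 10 rose and 7 fell, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.113). The kainate receptor subunits GRIK1 (4.80 ± 0.18) and GRIK4 (-3.90 ± 0.22) went opposite ways, GRIA3 (1.82 ± 0.12) rose and GRM2 (-3.08 ± 0.19) fell. Of 17 GABA and glycine receptor genes 4 rose and 7 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.679; median 0.04, mean -0.18, test direction lower). GABRA5 (2.92 ± 0.12) rose and GLRA3 (-3.94 ± 0.24), GABRB1 (-1.21 ± 0.12) and GABRD (-1.89 ± 0.20) fell. Of 28 monoamine and acetylcholine receptor genes 10 rose and 6 fell, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.147). The serotonin receptor genes HTR1E (4.92 ± 0.30), HTR2A (3.42 ± 0.25) and HTR1B (1.97 ± 0.16) rose and HTR1F (-2.84 ± 0.21) fell. Adjusted p by edgeR for the genes above ran from 4.11e-05 to 0.0013.

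Axon guidance genes leaned higher in RA glutamatergic neurons: 17 of 40 rose, 11 fell and 12 did not pass, or 18 and 13 adjusted over the list alone (median log2 0.35, camera adjusted p = 0.0137; adjusted p = 0.618 with an estimated correlation). The semaphorins SEMA3D (log2 5.17 ± 0.15 SE) and SEMA3E (-3.88 ± 0.17) went opposite ways, and EPHB1 (3.94 ± 0.14) and SLIT3 (3.27 ± 0.15) rose. Trophic factors and receptors also leaned higher, with 10 of 23 up and 4 down, or 12 and 5 adjusted over the list alone (median 0.65, camera adjusted p = 0.00759; adjusted p = 0.618 with an estimated correlation). IGF1 (5.33 ± 0.16), the GDNF receptor RET (2.79 ± 0.20), GDNF (2.23 ± 0.33) and IGFBP2 (1.46 ± 0.21) rose. Of 22 cadherins 8 rose and 5 fell, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.907). CDH8 (1.34 ± 0.15) and CDH10 (0.94 ± 0.11) rose and CDH18 (-2.02 ± 0.13) and CDH9 (-2.00 ± 0.14) fell. Of 34 cortical layer transcription factors 12 rose and 12 fell, or 14 and 13 adjusted over the list alone (camera adjusted p = 0.310). Besides TSHZ3, ETV1 (3.84 ± 0.14) and NFIB (3.10 ± 0.12) rose and DACH2 (-5.35 ± 0.18) fell. By edgeR the adjusted p of these genes ran from 2.34e-05 to 0.00425.

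Neuropeptides and their receptors leaned lower in RA glutamatergic neurons, with 5 of 30 up and 13 down, or 5 and 14 adjusted over the list alone (median log2 -0.76, camera adjusted p = 0.00962; adjusted p = 0.618 with an estimated correlation). NTS (-3.35 ± 0.16 SE), CCK (-5.20 ± 0.27) and the pentraxin NPTX1 (-2.50 ± 0.15) fell and the neuropeptide Y receptor NPY5R (1.98 ± 0.16) rose. Activity-induced genes fell in 6 of 16 and rose in 0, or 6 and 0 adjusted over the list alone (median -0.66, camera adjusted p = 0.0120; adjusted p = 0.618 with an estimated correlation), among them NPTX2 (79.2 ± 12.4 CPM in HVC and 4.95 in RA), EGR2 (-3.47 ± 0.45), GADD45B (-2.08 ± 0.26) and EGR3 (-1.62 ± 0.16). Of 19 steroid and retinoid signalling genes 3 rose and 4 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.708). THRB (1.77 ± 0.11) and RARB (1.65 ± 0.17) rose and ALDH1A2 fell. Of 16 calcium-binding protein genes 4 rose and 6 fell, or 4 and 7 adjusted over the list alone (camera adjusted p = 0.443). PCP4 (3.27 ± 0.20) rose and NRGN (-2.68 ± 0.26), NCS1 (-2.06 ± 0.15) and HPCAL1 (-1.07 ± 0.15) fell. Across these genes the edgeR adjusted p ran from 0.000125 to 0.00339.

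Mitochondrial transcripts were lower in RA glutamatergic neurons in 9 of 11 genes and higher in 1, and likewise adjusted over the list alone (median log2 -0.82, camera adjusted p = 0.0183; adjusted p = 0.618 with an estimated correlation), among them COX1 (-1.22 ± 0.19 SE), ND2 (-0.99 ± 0.15), COX3 (-0.95 ± 0.17) and ND5 (-0.93 ± 0.15). The mitochondrial share of UMIs in these nuclei was 0.440% ± 0.0573 in HVC and 0.231% in RA. Their median UMIs were 4077 ± 202 in HVC and 6682.5 in RA. A lower share of a larger total need not mean fewer mitochondrial UMIs per nucleus, and these changes are relative to the total. Of 16 heat shock and dissociation stress genes 1 rose and 5 fell, the same counts adjusted over the list alone (camera adjusted p = 0.348), with HSPB1 (-3.94 ± 0.79), DDIT3 (-2.41 ± 0.29), HSPE1 (-1.12 ± 0.17) and HSPH1 (-1.08 ± 0.15) down. Of 11 immature neuron genes 2 rose and 3 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.158). STMN1 (-2.70 ± 0.18) and ST8SIA4 (-1.73 ± 0.16) fell and DCX (1.04 ± 0.15) and ST8SIA2 (1.55 ± 0.26) rose. STMN1 also fell in every other class tested. Glial lists were tested as signs of other cells' RNA. Of 8 astrocyte reactivity genes 0 rose and 5 fell, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.130), including VIM (-3.06 ± 0.25) and STAT3 (-0.98 ± 0.20). Of 13 myelination genes 2 rose, among them UGT8 (1.39 ± 0.30), and 0 fell, the same counts adjusted over the list alone (camera adjusted p = 0.245). The genes named here had edgeR adjusted p from 0.00024 to 0.0176.

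**Figure D3:**
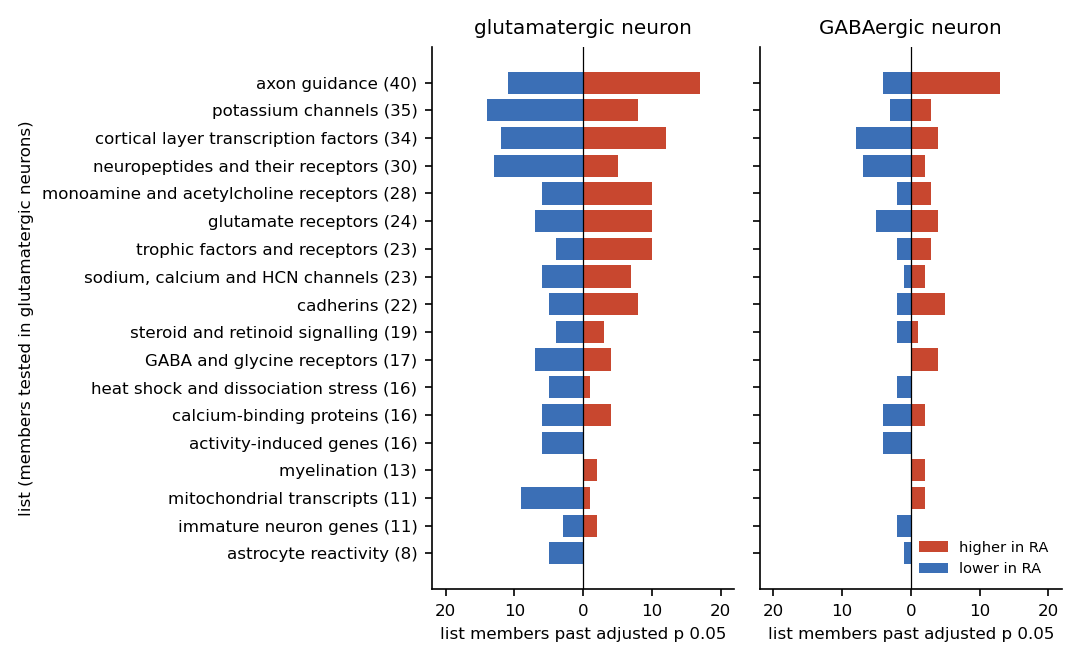
Number of members of each fixed list that were higher (right) or lower (left) in RA past an edgeR adjusted p of 0.05, in glutamatergic and GABAergic neurons, with the members tested in glutamatergic neurons in parentheses. Axon guidance had 17 higher and 11 lower in glutamatergic neurons, and 13 and 4 in GABAergic neurons.

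GABAergic neurons differed in 1287 of 12207 genes (10.5%), with 422 higher and 865 lower in RA (edgeR adjusted p under 0.05). Among genes with a mean of at least 20 CPM, the largest falls were in NRN1, a neurite growth protein, from 166 ± 21.9 CPM (SD, n = 3) to 5.51 CPM (log2 -4.89 ± 0.28 SE, edgeR adjusted p = 1.01e-06), the olfactory-type ion channel subunit CNGA2 (-3.99 ± 0.56), the peptide NTS (-3.81 ± 0.22) and the calcium pump regulator PLN (-3.61 ± 0.43). GABARAP (-3.19 ± 0.42), LRTM1 (-2.96 ± 0.38), GRINA (-2.91 ± 0.32) and CD164L2 (-2.79 ± 0.32) followed, all with edgeR adjusted p from 1.01e-06 to 0.00318. Higher in RA were SLC4A11 (2.32 ± 0.25), the collagen COL25A1 (2.19 ± 0.20), the protease ADAMTS18 (2.16 ± 0.22), SVIL (1.97 ± 0.40), ND6 (1.92 ± 0.23), ANOS1 (1.80 ± 0.23), PDZRN4 (1.78 ± 0.22) and the proteoglycan VCAN (1.77 ± 0.21), with edgeR adjusted p from 5.55e-05 to 0.0216. NRN1, NTS and SLC4A11 were more abundant in glutamatergic neurons, at 942, 557 and 585 CPM in the region with more, and free RNA reaches GABAergic droplets. The glutamatergic marker SLC17A6 was at 17.1% of its glutamatergic level there in HVC and 9.91% in RA. The glutamate transporter SLC1A2 was at 2.94% of its astrocyte level there in HVC and 5.50% in RA. SLC4A11 stood at 14.1% of its glutamatergic level in RA, SVIL at 11.4% and COL25A1 and ANOS1 at 30.4%. Free RNA is not ruled out for these genes or for NRN1 and NTS. ADAMTS18, PDZRN4, ND6 and VCAN stood at 118% to 1332% of their glutamatergic level. No such percent was taken for the genes that fell. Of the 1287 genes 850 were at least as high in GABAergic as in glutamatergic neurons. The count was 807 without HVC library 1 and 2133 without library 3, and 622 with DESeq2. SVIL no longer passed without library 1 (edgeR adjusted p = 0.124).

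Axon guidance genes rose in 13 of 39 and fell in 4 in GABAergic neurons, or 15 and 5 adjusted over the list alone (median log2 0.25, camera adjusted p = 0.00176; adjusted p = 0.618 with an estimated correlation). The SLIT receptor ROBO2 fell from 4057 ± 397 CPM (SD, n = 3) to 1538 (-1.40 ± 0.13 SE), and SEMA3C (2.37 ± 0.28), NRP2 (1.50 ± 0.22) and SLIT1 (1.33 ± 0.19) rose. GABA and glycine receptor genes rose in 4 of 17 and fell in 0, or 4 and 1 adjusted over the list alone (median 0.15, camera adjusted p = 0.0309; adjusted p = 0.618 with an estimated correlation), among them GABRA5 (1.62 ± 0.27), GLRA2 (0.69 ± 0.15) and GABBR1 (0.57 ± 0.14). The call was lost without HVC library 2 (camera adjusted p = 0.0534). The share of CGE-like cells was higher in RA (20.9% against 8.55%), and they had more GLRA2 than MGE-like cells in HVC (239 and 44.2 CPM). In subclasses fitted 1 by 1, after the data were seen, GLRA2 passed in LGE-like nuclei (log2 0.74 ± 0.22, edgeR adjusted p = 0.0419) but not in MGE-like (0.38 ± 0.26, adjusted p = 0.397) or CGE-like nuclei (adjusted p = 0.999). GABRA5 passed in LGE-like (edgeR adjusted p = 0.0470) and MGE-like nuclei (0.00129) and GABBR1 in MGE-like nuclei alone (0.0146). Neuropeptides and their receptors fell in 7 of 29 and rose in 2, or 10 and 4 adjusted over the list alone (median -0.54, camera adjusted p = 0.00313; adjusted p = 0.618 with an estimated correlation). NTS, CCK (-3.39 ± 0.43) and NPTX1 (-1.66 ± 0.16) fell and VIP (1.75 ± 0.30) rose. Of the subclasses VIP had enough counts for a fit in MGE-like nuclei alone (8.79 CPM in HVC and 55.3 in RA, log2 2.44 ± 0.33). Activity-induced genes fell in 4 of 15 and rose in 0, or 6 and 0 adjusted over the list alone (median -0.93, camera adjusted p = 0.00377; adjusted p = 0.632 with an estimated correlation). These were NPTX2 (-2.41 ± 0.34), GADD45B (-1.43 ± 0.28), EGR3 (-1.38 ± 0.22) and EGR2, which had 3 counts in RA (6.15-fold lower, counting interval 2.02 to 30.6) and did not pass without library 1 (edgeR adjusted p = 0.131). Myelination genes rose in 2 of 12 and fell in 0, or 4 and 0 adjusted over the list alone (median 0.80, camera adjusted p = 0.00075; adjusted p = 0.618 with an estimated correlation), among them ENPP2 (1.02 ± 0.25), which did not pass without library 1 (edgeR adjusted p = 0.0660) or in any subclass fitted alone (adjusted p of at least 0.115). Of the genes that fell, 2 of 7 neuropeptide and 1 of 4 activity-induced genes were at least as high in GABAergic as in glutamatergic neurons. Of those that rose, 8 of 13 axon guidance, 2 of 4 GABA and glycine receptor and 2 of 2 myelination genes were. The genes named here had edgeR adjusted p from 1.01e-06 to 0.0359.

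No other list was called in GABAergic neurons. For potassium channels 3 of 35 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.650; median -0.02, mean -0.05, test direction higher), with KCND2 up (1.09 ± 0.14 SE). Sodium, calcium and HCN channels had 2 of 23 up and 1 down, the same adjusted over the list alone (adjusted p = 0.499; median -0.03, mean 0.10). Glutamate receptors had 4 of 25 up and 5 down, or 6 and 5 adjusted over the list alone (camera adjusted p = 0.659; median -0.07, mean -0.11, test direction higher). GRIK1 (1.16 ± 0.14) and GRM3 (0.85 ± 0.15) rose and GRM2 (-2.91 ± 0.50) and CACNG3 (-1.12 ± 0.21) fell. Cadherins had 5 of 22 up and 2 down, or 6 and 4 adjusted over the list alone (adjusted p = 0.143). CDH19 (1.21 ± 0.23) and PCDH17 (0.98 ± 0.17) rose and PCDH9 (-0.67 ± 0.11) fell. Cortical layer transcription factors had 4 of 34 up and 8 down, or 4 and 9 adjusted over the list alone (adjusted p = 0.706; median -0.01, mean 0.01, test direction lower). NR4A2 (3.63 ± 0.39) rose and ID2 (-2.43 ± 0.34), DACH2 (-1.35 ± 0.22) and BCL11A (-0.85 ± 0.15) fell. Calcium-binding proteins had 2 of 16 up and 4 down, or 2 and 5 adjusted over the list alone (adjusted p = 0.0668). NRGN (-2.56 ± 0.31) fell and NECAB2 (0.85 ± 0.19) rose. Trophic factors had 3 of 22 up and 2 down, or 6 and 3 adjusted over the list alone (adjusted p = 0.416; median 0.12, mean -0.10). FGFR2 (1.04 ± 0.21) and IGF1 (0.92 ± 0.16) rose and FGF1 (-1.66 ± 0.30) fell. FGFR2 did not pass with list genes used for clustering (0.73, edgeR adjusted p = 0.0573), and of the subclasses it passed in MGE-like nuclei alone (2.05 ± 0.32, with 0.79 in LGE-like and 0.19 in CGE-like nuclei). The genes named here had edgeR adjusted p from 0.000148 to 0.014.

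Steroid and retinoid signalling genes in GABAergic neurons rose in 1 of 15 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.719; median 0.07, mean -0.27, test direction lower), with ALDH1A2 (log2 -2.07 ± 0.26 SE) and the estrogen receptor ESR1 (-1.51 ± 0.37) down. Monoamine and acetylcholine receptors rose in 3 of 27 and fell in 2, or 3 and 3 adjusted over the list alone (adjusted p = 0.710; median -0.02, mean -0.15, test direction higher). HTR2A (2.12 ± 0.32) rose and CHRM4 (-1.18 ± 0.26) fell. Immature neuron genes fell in 2 of 11 and rose in 0, the same adjusted over the list alone (adjusted p = 0.130), namely STMN1 (-2.19 ± 0.19) and SOX4 (-1.25 ± 0.26). Astrocyte reactivity genes fell in 1 of 8, VIM (-2.15 ± 0.35), and rose in 0, or 3 and 0 adjusted over the list alone (adjusted p = 0.0889). Heat shock and dissociation stress genes fell in 2 of 15 and rose in 0, the same adjusted over the list alone (adjusted p = 0.842; median 0.08, mean -0.16), with DDIT3 (-1.43 ± 0.30) among them. Mitochondrial transcripts rose in 2 of 11, ND6 among them, and fell in 0, the same adjusted over the list alone (adjusted p = 0.359; median -0.13, mean 0.12), with a mitochondrial share of UMIs of 0.571% ± 0.0958 in HVC and 0.527% in RA. The genes named here had edgeR adjusted p from 3.82e-05 to 0.0203. With another scaling the sign of the median or mean turned for potassium channels, cortical layer transcription factors and monoamine receptors in GABAergic neurons. With DESeq2 the calls for ESR1 and CHRM4 were lost. STMN1 and VIM were called lower in RA in every class tested, glia and vascular cells included. RA is 1 library, so for them a difference between regions cannot be told from a shift of that library.

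The change between regions differed between glutamatergic and GABAergic neurons in 1935 of 13340 genes (14.5%; edgeR interaction, library as a block, adjusted p under 0.05), 1122 with a higher and 813 with a lower value in glutamatergic neurons. Among the 1912 of them fitted in both classes, the change was larger in glutamatergic neurons for 87.1%. TSHZ3 was 6.85 ± 0.24 (log2, SE) higher in its change in glutamatergic neurons (edgeR adjusted p = 1.32e-07), with a change of -0.15 in GABAergic neurons (adjusted p = 0.593). LAMA3 (6.25 ± 0.21), NDNF (6.56 ± 0.57) and PTCHD4 (5.89 ± 0.14) followed the same direction, with edgeR adjusted p from 4.27e-11 to 0.00136. The chromatin organizer SATB1 fell by 4.58 in glutamatergic neurons and rose by 0.87 in GABAergic neurons, a difference of -5.46 ± 0.17 (edgeR adjusted p = 3.33e-10). LGR6, with 2 RA counts in glutamatergic neurons, had a fitted difference of -8.24 ± 0.97 (edgeR adjusted p = 0.000405) and a change of -0.60 in GABAergic neurons (adjusted p = 0.641). Without the block 761 genes passed, and 1034 with DESeq2.

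Each class of glia and vascular cells differed in fewer genes than glutamatergic neurons: 1373 of 11587 in astrocytes (513 higher and 860 lower in RA), 940 of 8484 in oligodendrocytes (344 and 596), 804 of 8205 in endothelial cells (397 and 407), 301 of 7238 in oligodendrocyte precursors (95 and 206) and 182 of 3252 in microglia (106 and 76), by edgeR with adjusted p under 0.05. With DESeq2 the counts were 601, 146, 143, 51 and 23. Astrocytes lay in clusters 2 and 32 in HVC and 4 in RA, oligodendrocytes in 10 and 18 and endothelial cells in 7 and 24. The p-values below in oligodendrocytes, endothelial cells, precursors and microglia rest mostly on a spread shared over genes, not on each gene's own. In astrocytes SLC4A11 (log2 5.73 ± 0.33 SE), PDE5A (4.32 ± 0.31), COL25A1 (3.79 ± 0.35) and the potassium channel KCNB2 (3.68 ± 0.19) rose, with edgeR adjusted p from 6.66e-06 to 0.000158. They stood at 18.2% to 26.5% of their glutamatergic level in RA, a comparison chosen after the data were seen, and SLC17A6 stood at 19.3% there, so free RNA is not ruled out for them. FNDC9, UTS2B and FGL2 had 0 counts in RA astrocytes and were at least 32.4-fold, 23.0-fold and 18.8-fold lower, and CCK, with 3 counts, was 30.9-fold lower (counting interval 10.4 to 151). In oligodendrocytes TMEM200A rose (4.95 ± 0.51, edgeR adjusted p = 4.37e-19), and ANOS1, SLC4A11 and RSPO3, with 3 HVC counts or fewer, were 85.0-fold (14.7 to 3412), 72.0-fold (19.4 to 603) and 30.7-fold (10.1 to 153) higher. These 4 stood at 22.8% to 45.7% of their glutamatergic level in RA, and SLC17A6 at 16.7%. FNDC9, UTS2B, CCK and FGL2 were at 0 counts in RA oligodendrocytes and at least 13.9-fold, 10.6-fold, 9.72-fold and 9.03-fold lower. No percent of the glutamatergic level was taken for genes that fell. FNDC9, UTS2B and CCK also fell in glutamatergic neurons, and free RNA is not ruled out for their falls here. Of these CCK was at least as high in astrocytes, oligodendrocytes and endothelial cells as in glutamatergic neurons. DESeq2 did not call SLC4A11 in oligodendrocytes (adjusted p = 0.570), and ANOS1 did not pass there with at least 1000 genes per nucleus (edgeR adjusted p = 0.166).

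In endothelial cells TMEM200A (log2 5.01 ± 0.48 SE), MRVI1 (3.99 ± 0.56) and PTCHD4 (3.88 ± 0.31) rose (edgeR adjusted p from 2.83e-20 to 7.08e-08), NR4A2, with 1 HVC count, was 95.5-fold higher (16.1 to 3880), and FAM43B, FNDC9, CCK and CBLN2, at 0 counts in RA, were at least 7.82-fold, 7.45-fold, 6.96-fold and 5.01-fold lower. In oligodendrocyte precursors PDE5A (3.21 ± 0.59) and TMEM200A (3.05 ± 0.53) rose (edgeR adjusted p from 3.61e-05 to 0.000105), SLC4A11 was 69.9-fold (11.6 to 2851) and MRVI1 23.3-fold (7.24 to 119) higher, and PSENEN, AP1B1, CNGA2 and FNDC9 were at least 5.15-fold, 5.01-fold, 4.72-fold and 4.58-fold lower. The 4 genes that rose in precursors stood at 14.1% to 24.7% of their glutamatergic level in RA, where SLC17A6 stood at 18.3%. In microglia TSHZ3 (4.24 ± 0.54), KLHL1 (4.04 ± 0.90) and KCNB2 (3.55 ± 0.45) rose (edgeR adjusted p from 3.71e-12 to 0.000518), TMEM200A was 81.2-fold higher (12.6 to 3407), and NTS, CTXN1, COX7B and NRN1L were at least 13.3-fold, 4.46-fold, 3.81-fold and 3.48-fold lower. The genes that rose stood at 24.7% to 59.1% of their glutamatergic level in RA endothelial cells and 54.2% to 92.7% in RA microglia, with SLC17A6 at 28.1% and 29.5%. Genes that fell in these classes were not compared in this way, and free RNA is not ruled out for them. TMEM200A, COX7B and NRN1L lost their calls in microglia without HVC library 1, and TMEM200A also without library 2. COX7B did not pass at resolution 0.5 (edgeR adjusted p = 0.349), nor did PDE5A (0.0840) and CNGA2 (0.0699) in precursors with at least 1000 genes per nucleus. Of the calls, 874 in astrocytes, 599 in oligodendrocytes, 474 in endothelial cells and 94 in microglia were of genes at least as high there as in glutamatergic neurons. Calls shared with glutamatergic neurons were counted after the data were seen. Of the GABAergic calls 277 of 421 higher and 685 of 865 lower in RA were also called that way in glutamatergic neurons, among genes tested in both, where independent lists would share 64.3 and 139.7. The numbers were 377 of 512 and 680 of 857 in astrocytes (79.4 and 143 if independent), 249 of 343 and 503 of 594 in oligodendrocytes (61.1 and 109), and 266 of 397 and 322 of 407 in endothelial cells (71.7 and 77.2). In precursors they were 77 of 95 and 175 of 206 (18.9 and 39.1) and in microglia 82 of 106 and 67 of 76 (25.4 and 16.5). All classes come from the same libraries. Without HVC library 1 the counts were 530 in oligodendrocytes, 184 in precursors and 55 in microglia. Astrocytes had 2133 without library 2 and 2070 without library 3, and microglia 115 without library 2.

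Neuropeptides fell in astrocytes (7 of 25 down and 2 up, or 10 and 3 adjusted over the list alone; camera adjusted p = 0.000665), as did activity-induced genes (5 of 14 down and 0 up, or 6 and 0 adjusted over the list alone; camera adjusted p = 0.0031), and axon guidance genes rose (15 of 37 up and 3 down, or 17 and 7 adjusted over the list alone; camera adjusted p = 0.000665). All had an adjusted p = 0.618 with an estimated correlation. In endothelial cells cadherins rose in 9 of 20 and fell in 0, or 12 and 1 adjusted over the list alone (camera adjusted p = 2.78e-07), and glutamate receptors rose in 9 of 24 and fell in 2, or 12 and 2 adjusted over the list alone (camera adjusted p = 4.93e-07). Both had an adjusted p = 0.618 with an estimated correlation. Of the 15 axon guidance genes that rose in astrocytes 0 were at least as high there as in glutamatergic neurons, and of the genes that rose in endothelial cells 0 of 9 glutamate receptors and 2 of 9 cadherins were. Further camera calls were for higher myelination (adjusted p = 0.00112), GABA and glycine receptor (0.0145), glutamate receptor (0.0192) and cortical transcription factor genes (0.0467) and lower immature neuron genes (0.0406) in astrocytes, with adjusted p = 0.657 for GABA and glycine receptors and 0.618 for the others with an estimated correlation. At least as high in astrocytes as in glutamatergic neurons were 3 of 3 myelination, 2 of 6 GABA and glycine receptor, 0 of 4 glutamate receptor and 2 of 5 cortical transcription factor genes that rose. In endothelial cells they were for higher myelination (adjusted p = 0.00112), axon guidance (0.00384), GABA and glycine receptor (0.00507), trophic factor (0.00618) and cortical transcription factor genes (0.0363) and lower neuropeptides (0.00384) and activity-induced genes (0.00414), all with adjusted p = 0.618 with an estimated correlation. Of the axon guidance genes in endothelial cells 8 rose and 4 fell, and 0 of these were at least as high there as in glutamatergic neurons. Of those that rose, 3 of 3 myelination, 1 of 4 GABA and glycine receptor, 3 of 7 trophic factor and 0 of 6 cortical transcription factor genes were. Microglia had higher cadherins (camera adjusted p = 0.000551), glutamate receptors (0.000665) and GABA and glycine receptors (0.0406) and lower neuropeptides (0.00112), all with adjusted p = 0.618 with an estimated correlation. By gene 3 of 18 cadherins, 5 of 19 glutamate receptors and 0 of 11 GABA and glycine receptors rose in microglia, and 1, 1 and 0 of these were at least as high there as in glutamatergic neurons. Oligodendrocytes had lower neuropeptides (camera adjusted p = 0.00112), activity-induced (0.00739) and immature neuron genes (0.0406) and higher GABA and glycine receptors (0.0406), and precursors lower immature neuron genes (camera adjusted p = 0.000665), neuropeptides (0.00396) and activity-induced genes (0.00416), and these too had an adjusted p = 0.618 with an estimated correlation. Of the 5 GABA and glycine receptor genes that rose in oligodendrocytes 0 were at least as high there as in glutamatergic neurons. Of genes that fell in astrocytes, 3 of 7 neuropeptide, 1 of 5 activity-induced and 2 of 2 immature neuron genes were. The numbers in that order were 4 of 6, 3 of 5 and 1 of 1 in oligodendrocytes and 2 of 5, 1 of 2 and 2 of 2 in precursors. In endothelial cells 4 of 5 neuropeptide and 3 of 4 activity-induced genes were, and in microglia 3 of 3 neuropeptide genes. Over all classes 38 of 123 pairs of list and class passed, and 0 did with an estimated correlation. Calls lost with 1 library left out were cortical transcription factors (0.101 without library 2) and immature neuron genes (0.0534 without library 2 and 0.0825 without library 3) in astrocytes, and cortical transcription factors (0.111 without library 1), activity-induced genes (0.0776 without library 3) and trophic factors (0.0534 without library 2) in endothelial cells. Also lost were GABA and glycine receptors in microglia (camera adjusted p = 0.357 without library 1 and 0.180 without library 2) and, in oligodendrocytes, GABA and glycine receptors (0.213 without library 1 and 0.054 without library 2) and immature neuron genes (0.0559 without library 2).

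**Figure D4:**
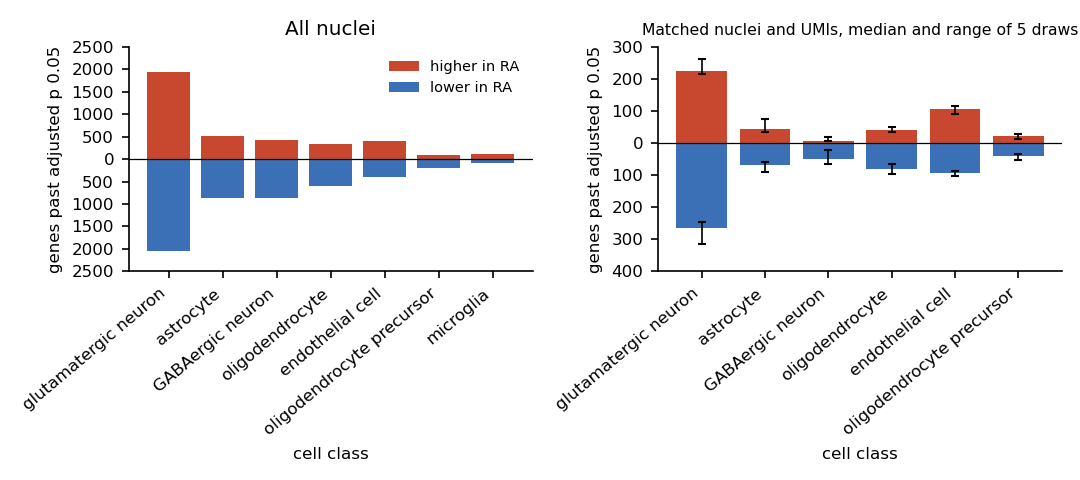
Genes higher (above 0) or lower (below 0) in RA past an edgeR adjusted p of 0.05 in each class, from all nuclei (left) and from equal nuclei and UMIs per class and library (right; bars are medians of 5 draws and error bars their range). At equal depth the total was 482 genes in glutamatergic neurons and 63 in GABAergic neurons.

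Since classes differ in nuclei and UMIs, counts were also compared at 104 nuclei per library and class. Then 482 genes passed in glutamatergic neurons, 199 in endothelial cells, 121 in oligodendrocytes, 113 in astrocytes, 63 in GABAergic neurons and 59 in oligodendrocyte precursors (edgeR, medians of 5 draws). With neurons matched alone, chosen after the data were seen, 2512 passed in glutamatergic and 899 in GABAergic neurons. Distances in expression were largest in glutamatergic neurons and smallest in GABAergic neurons: RA and HVC libraries of glutamatergic neurons lay 1.21 ± 0.0157 (SD of 3 pairs) apart in root mean square log2 CPM, and HVC libraries 0.870 ± 0.0053 from each other, a ratio of 1.39. That ratio was 2.15 at a minimum of 100 CPM. Depth changed along with other choices in 2 settings: the ratio was 1.19 with doublets kept, where 55 nuclei per library and class were drawn, and 2.94 with neurons matched alone, with 503 nuclei. The last was chosen after the data were seen. In it HVC libraries of glutamatergic neurons lay 0.292 from each other, so most of the 0.870 at 104 nuclei came from few nuclei and UMIs. The excess, the root of the difference between the squared mean distances, moved less. It was 0.834 in glutamatergic neurons, 0.856 with doublets kept and 0.808 with neurons matched alone. In endothelial cells the distances were 1.04 and 0.871. The ratios were 1.18 in oligodendrocytes, 1.17 in astrocytes, 1.13 in oligodendrocyte precursors and 1.11 in GABAergic neurons, where the distances were 0.963 ± 0.0109 and 0.866 ± 0.006 (a ratio of 1.76 with neurons matched alone). Pairs share libraries, so no test was made.

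**Figure D5:**
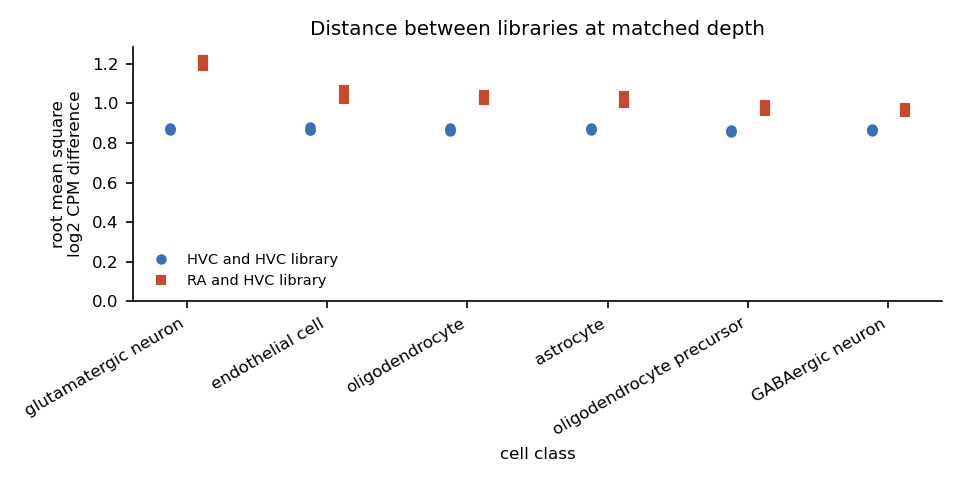
Root mean square log2 CPM difference between pairs of libraries at equal nuclei and UMIs, with circles for pairs of HVC libraries and squares for pairs of the RA library and an HVC library. Glutamatergic neurons stood highest, at a mean of 1.21 for RA against 0.870 within HVC.

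Within HVC, glutamatergic nuclei were clustered again, and 6 subclusters had enough nuclei in every library to compare list genes with the remaining nuclei. Of 357 list genes tested in subcluster 1, 103 were higher and 119 lower (edgeR adjusted p under 0.05), led by the AMPA receptor subunit GRIA4 (log2 2.86 ± 0.08 SE) and KCND2 (2.77 ± 0.13) with CYP19A1, the estrogen-forming aromatase (2.37 ± 0.48), and by falls in GFRA1 (-3.18 ± 0.11), KCNQ5 (-3.16 ± 0.11) and ALDH1A2 (-3.15 ± 0.13). CYP19A1 did not pass without library 1 (edgeR adjusted p = 0.360). Subcluster 10 had 115 higher and 117 lower. NECAB2 (3.04 ± 0.23), CACNA1G (2.79 ± 0.08) and the tachykinin TAC1 (2.74 ± 0.21) rose and ALDH1A2 (-2.65 ± 0.12) and GRM2 (-2.42 ± 0.18) fell. Subcluster 11 had 97 higher and 131 lower. RET (5.56 ± 0.14), the polysialyltransferase ST8SIA2 (4.58 ± 0.21) and the neurotrophin NTF3 (4.04 ± 0.34) rose and GRM8 (-2.71 ± 0.14), THRB (-2.48 ± 0.17) and SEMA3E (-2.43 ± 0.17) fell. Subcluster 12 had 90 higher and 93 lower. SLIT3 (3.61 ± 0.11), SEMA3D (3.37 ± 0.31) and CCK (3.18 ± 0.13) rose and KCNQ5 (-3.44 ± 0.19), GFRA1 (-3.16 ± 0.15) and SEMA5B (-3.05 ± 0.33) fell. Subcluster 6 had 66 higher and 111 lower. HTR2A (2.54 ± 0.34) and GRM8 (2.09 ± 0.33) rose and KCND2 (-2.80 ± 0.31) and CDH22 (-2.80 ± 0.35) fell. Subcluster 2 had 4 higher and 55 lower, among them CACNA1G (-4.11 ± 0.31) and GABRG3 (-3.17 ± 0.28). Its nuclei from the first cluster 0 were 121, 921 and 24 in libraries 1, 2 and 3 (86.4% from library 2). Without library 2, 22 genes passed, and 27 with DESeq2. The rises in GLRA3 (0.88 ± 0.22), VIPR1 (0.71 ± 0.21) and GABRG1 (0.69 ± 0.22) in subcluster 2 were lost under several settings. With the first clusters in place of subclusters, an alternative chosen after the data were seen, the genes higher and lower were 93 and 127 in cluster 0, 101 and 108 in cluster 3, 102 and 140 in cluster 6, 107 and 115 in cluster 16, 97 and 77 in cluster 26 and 83 and 134 in cluster 27 (edgeR adjusted p under 0.05).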

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

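The change between RA and HVC differed between glutamatergic and GABAergic neurons in 1935 genes in the edgeR interaction test. These were picked out because the 2 neuron classes of the same libraries gave different changes. The 6 largest were LGR6 (log2 -8.24), TSHZ3 (6.85), NDNF (6.56), LAMA3 (6.25), PTCHD4 (5.89) and SATB1 (-5.46). LGR6 rests on 2 counts in RA glutamatergic neurons. SATB1 was the only 1 of the 6 with a passing change of the opposite sign in GABAergic neurons.

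Cluster 15, with 634 HVC nuclei, belonged to no class in the comparisons because its astrocyte markers were weak (score 0.368). Its leading genes were TNC, GDF10, COL22A1, CPA6 and ARAP2, and it had 299, 194 and 141 nuclei in the HVC libraries and 0 in RA.

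Both tests in this paragraph were chosen after the result was seen. Cluster 1 held 3990 barcodes of HVC library 3, which is 46.0% of that library, with a median of 3220.5 UMIs and a mitochondrial share of 1.82%, against 2994 UMIs and 0.702% in its named nuclei. RNA of many cell types in 1 droplet would put markers of most classes at 10% or more of their own level; 3 of 7 classes reached it (glutamatergic 104%, GABAergic 30.7% and astrocyte 13.8%) and 7 of 7 were above cluster 0 of the library, which leaves this open. With 2 nuclei in 1 droplet the UMIs would be well above those of named nuclei; the ratio was 1.08, and glutamatergic nuclei of the library had a median of 3911, which leaves this open as well. No biological explanation was tested.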

How the results depend on the processing

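No paired analysis was possible for RA against HVC because RA has 1 library and the libraries share no pairing. For the fits with the library as a block, leaving out the block gave 761 interaction genes and, for HVC subclusters 1, 2, 6, 10, 11 and 12, 155, 32, 133, 171, 186 and 141 list genes. Of 239 named gene results 0 changed direction under any setting in which they were tested. Of 38 list results 0 did with RLE size factors, an estimated correlation, fry or 1 HVC library left out. Lists were not run with a direction under the other settings. Calls of named genes were lost in 17 of 213 with DESeq2, 26 of 71 at equal depth, 7 of 184 with at least 1000 genes per nucleus, 22 of 238 without HVC library 1, 6 of 239 without library 2 and 3 of 239 without library 3. The list calls fell to 0 of 38 with an estimated correlation and 0 with fry, while fry without regard to direction gave 107. Leaving out 1 library left 33 to 41 list calls. No list's median changed with genes at 0 counts set to their limit. Endothelial cells and microglia could not be tested with at least 1000 genes per nucleus, nor microglia at equal depth. The cause was not tested for any change given here, except where fewer nuclei or UMIs were used by construction.

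Leaving out 1 HVC library gave, from lowest to highest, 2571 to 4449 genes in glutamatergic neurons, 807 to 2133 in GABAergic neurons, 1021 to 2133 in astrocytes, 543 to 1001 in endothelial cells, 530 to 1044 in oligodendrocytes, 184 to 413 in oligodendrocyte precursors, 55 to 207 in microglia, 1403 to 2140 for the interaction and 22 to 67 in subcluster 2. With DESeq2 there were 622 genes in GABAergic neurons, 601 in astrocytes, 143 in endothelial cells, 146 in oligodendrocytes, 51 in oligodendrocyte precursors, 23 in microglia, 1034 for the interaction and 27 in subcluster 2. At equal nuclei and UMIs the counts were 482 in glutamatergic and 63 in GABAergic neurons, 113 in astrocytes, 199 in endothelial cells, 121 in oligodendrocytes and 59 in precursors, and 2512 in glutamatergic and 899 in GABAergic neurons with neurons matched alone. At least 1000 genes per nucleus gave 893 in astrocytes and 208 in oligodendrocytes; microglia had 100 with no filter on low counts and 539 at resolution 0.5. Calls at least as high as in glutamatergic neurons were 850 in GABAergic neurons, 874 in astrocytes, 474 in endothelial cells, 599 in oligodendrocytes and 94 in microglia.

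Leaving out 1 library gave log2 shares of 1.24 to 1.41 for CGE-like, -0.66 to -0.255 for LGE-like, -0.0760 to 0.10 for MGE-like and -0.67 to -0.29 for unnamed subclasses, and of 1.14 to 1.62 for astrocytes, -0.80 to -0.36 for glutamatergic neurons, 1.53 to 2.26 for oligodendrocytes, 1.04 to 1.37 for oligodendrocyte precursors, -2.66 to -1.27 for unnamed nuclei and 0.77 to 1.61 for endothelial cells. The MGE-like share was -0.0659 with doublets kept and -0.0721 out of named subclasses, and the unnamed subclass share was -1.80 at resolution 1. Out of named nuclei the log2 shares were 0.99 for astrocytes, -0.94 for glutamatergic neurons, 1.46 for oligodendrocytes, 0.81 for oligodendrocyte precursors and -0.0575 for microglia. Oligodendrocytes stood at 1.91 with doublets kept, endothelial cells at -0.58 with at least 1000 genes and immature neurons at -2.06 at resolution 0.5.

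Distances with doublets kept were drawn at 55 nuclei per library and class, those with at least 1000 genes at 70 and those of neurons matched alone at 503, against 104 otherwise, so these settings also changed the depth. Ratios with doublets kept were 1.19 in glutamatergic neurons, 1.04 in GABAergic neurons, 1.08 in astrocytes, 1.10 in endothelial cells, 1.08 in oligodendrocytes and 1.06 in oligodendrocyte precursors. With at least 1000 genes they were 1.47 in glutamatergic neurons, 1.14 in GABAergic neurons, 1.21 in astrocytes and 1.17 in precursors. With a minimum of 100 CPM they were 2.15, 1.29, 1.38 and 1.29 in those classes, 1.45 in endothelial cells and 1.39 in oligodendrocytes. By Spearman distance they were 1.54 in glutamatergic neurons, 1.24 in endothelial cells and 1.22 in oligodendrocytes. Glutamatergic neurons had 1.33 without list genes, and neurons matched alone gave 2.94 in glutamatergic and 1.76 in GABAergic neurons.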

Other observations

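RA glutamatergic neurons fell into 2 clusters, 8 (824 nuclei) and 20 (540 nuclei), whose list genes differed widely. The kainate receptor gene GRIK1 was at 952 CPM (exact Poisson interval 927 to 977) in cluster 8 and 49.1 (42.1 to 57.0) in cluster 20, 19.4-fold apart, and VIPR1 (11.9-fold), IGF1 (8.51-fold) and SEMA6D (7.31-fold) were also higher in cluster 8. The potassium channel genes KCNK2 (26.4-fold) and KCNQ5 (18.2-fold), with EPHA4 (22.5-fold) and NTS (19.4-fold), were higher in cluster 20. With 1 library no test was made, and the intervals cover counting error only. GABAergic subclasses were fitted 1 by 1 after the data were seen, and no difference between subclasses was tested. NRP2 rose in CGE-like (log2 2.20 ± 0.42 SE) and MGE-like nuclei (2.14 ± 0.31) and had 0.41 ± 0.35 in LGE-like nuclei (edgeR adjusted p = 0.561). SEMA3C rose in MGE-like nuclei (3.01 ± 0.48) and had 0.06 ± 0.58 in CGE-like nuclei (edgeR adjusted p = 0.977), and IGF1 rose in LGE-like (3.51 ± 0.73) and MGE-like nuclei (0.93 ± 0.23). BCL11A fell in CGE-like (-1.22 ± 0.24) and MGE-like nuclei (-1.07 ± 0.16), with -0.20 ± 0.20 in LGE-like nuclei (edgeR adjusted p = 0.615). edgeR called 113 genes higher and 242 lower in CGE-like nuclei, 178 and 264 in LGE-like and 388 and 673 in MGE-like nuclei; DESeq2 called 16 and 47, 27 and 57, and 111 and 219.

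Some genes changed in a class where they were at least 2-fold above every other class, a rule chosen after the data were seen. In GABAergic neurons RELN (log2 0.94 ± 0.12 SE), ADARB2 (0.77 ± 0.10), KCNMB2 (1.26 ± 0.13) and NTN1 (2.04 ± 0.31) rose and MAF (-0.43 ± 0.11) fell. RELN and ADARB2 are markers of CGE-like cells, whose share of GABAergic nuclei was 8.55% in HVC and 20.9% in RA. In astrocytes KCNJ10 (-1.25 ± 0.22), HMGCS1 (-1.34 ± 0.18) and ACAN (-4.42 ± 0.81) fell and SMOC1 (1.13 ± 0.22) rose. In oligodendrocytes PLLP (-1.49 ± 0.30) fell and MAG (0.65 ± 0.23) and MYRF (0.69 ± 0.24) rose, and in microglia CD74 (-1.39 ± 0.36) and C1QB (-1.88 ± 0.44) fell. In endothelial cells VWF (-0.99 ± 0.26), ID1 (-1.74 ± 0.29), RAMP2 (-1.48 ± 0.29) and EDN1 (-1.78 ± 0.47) fell. Such genes were 33 lower and 4 higher in endothelial cells and 11 lower and 1 higher in microglia, where the astrocyte transporter SLC1A2 went from 5.53% of its astrocyte level in HVC to 14.2% in RA and from 5.37% to 17.0%. The edgeR adjusted p of these genes ran from 2.38e-06 to 0.0476.

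The tests of genes higher in RA and of oligodendrocyte precursors alone were chosen after the result was seen, and the others before. Of genes lower in RA outside glutamatergic neurons, 75.3% were at or above the class level in the mixed HVC droplets, against 56.2% of uncalled genes. Of those higher in RA 88.1% were higher in another class of the library, against 84.4% of uncalled genes. Neither decides whether RNA from other cells could be the cause. For genes higher in RA the classes went both ways. The share was above that of uncalled genes in microglia (93.4% and 61.0%), endothelial cells (95.0% and 79.1%), oligodendrocytes (88.1% and 79.5%) and precursors (91.6% and 86.9%). It was below it in GABAergic neurons (82.7% and 92.4%) and astrocytes (85.6% and 88.6%). As the only cause, such RNA was predicted to leave at most 5% of calls highest in the class itself. In these classes together 10.7% of calls were (9.56% of strict calls), past that limit, but so were 14.0% of uncalled genes. By class the share of calls was under that of uncalled genes in microglia (14.8% and 39.4%), endothelial cells (13.6% and 21.8%), oligodendrocytes (10.3% and 17.3%) and precursors (7.64% and 10.3%). It was over it in GABAergic neurons (8.62% and 5.50%) and astrocytes (11.3% and 9.97%). A change in the amount of other cells' RNA would also shift a class's own genes, so this does not decide it. In oligodendrocyte precursors 3.38% of strict calls were highest in the class itself (7.64% of all their calls), so it stays open there too. Of 4887 calls 178 were well above every other class (3.64%, against 2.55% of uncalled genes). False calls alone would give 14.8 at the largest simulated false rate of 11.9%. That simulation gave RA the same spread as the HVC libraries, so it cannot set the false rate of a lone RA library. The share of uncalled genes is the closer comparison. Over it, oligodendrocytes (3.51% and 3.91%), microglia (6.59% and 6.22%) and endothelial cells (4.60% and 3.84%) showed no clear excess.

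The test of a shift of whole libraries was chosen after the result was seen, and the others before. Of 5301 nuclei in HVC glutamatergic cluster 0, 80.4% lay in 6 subclusters that each came mostly from 1 library. With every nucleus at 2000 UMIs the share was 80.9% (80.8% unthinned), which argues against depth. A shift of whole libraries stays open: 1 library held 3 such subclusters, but 6 of them over 3 libraries put more than 1 in some library whatever the cause. Birds pooled within a library would carry the same signature genes into other clusters: in cluster 3 their excess correlation was 0.0155 in the same library and -0.00127 in the others, which is consistent with pooled birds. The same-library values were 0.0289 and 0.0508 in cluster 6 and 0.0187 and 0.0250 in cluster 16, but signatures of library 1 also passed the shuffled limit of 0.00843 in cluster 16 of library 3 (permutation p = 0.0330), and in GABAergic neurons the values were 0.00423 (permutation p = 0.0390) and 0.00335 (permutation p = 0.124).

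Both tests in this paragraph were chosen after the result was seen. Each HVC library set against the other 3 libraries gave 0 edgeR calls in glutamatergic neurons, and RA 3988. RA was among the other 3 and widened their spread, which leaves an HVC library little room for calls. Only 1 of 4 splits, the real one, was as high, but with 4 a share under 0.05 is out of reach. The same holds for list genes of the HVC subclusters: only 1 of 4 splits, the real one, was as high in each, with 4 higher and 55 lower in subcluster 2, the fewest, and at most 20 calls in the other splits of any subcluster.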
